A study of Arabidopsis thaliana with 2 samples.

How the data were processed

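Total RNA of rosette leaves from 1 sample of GFPox and 1 sample of GFP-LKP2ox plants was converted to Cy3-labelled cRNA from 100 ng of RNA and hybridised to Agilent one-colour arrays, per the labels' protocols. Spot intensity values were deposited as the scanner software wrote them: per the file headers, Agilent Feature Extraction version 10.7.3.1 subtracted the background, corrected a spatial trend within each array and replaced very low signals by surrogate values, with no normalisation between arrays. Other columns are flags of 0 or 1 set by the same software, per the file headers, for spots well above background, saturated spots and outlier spots. The authors' deposited value table holds a linear ratio, each spot's processed signal divided by the array's median signal (185 for GFPox and 169 for GFP-LKP2ox); set against the scanner values, the quotient was constant over all 43803 spots within rounding, each column's median was 1, and genes were not centred. It was used as an alternative, and its scale and direction are thereby known. Reads were not involved. The value table has 0 further sample columns.

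In the main setting the log2 of the processed signal was taken and each array's 75th percentile over the gene probes (1364 and 1212 in linear units) was subtracted. Control spots and 13 outlier spots were left out, spots of 1 probe were averaged, and 43599 probes remained. A probe counted as well above background on an array where most of its spots were, and entered if that held on at least 1 array, as for 30994 probes. Where it was dim on 1 array, the brighter value was set against the higher of the dim probe's own signal and the lowest signal well above background on that array (10.7 for GFPox and 11.6 for GFP-LKP2ox), giving an "at least" fold, and no value was used if that bound had the opposite sign. Where the dim probe's own signal was the higher, the fold is the observed ratio, and calling it a bound ignores the error of that dim signal. A gene's value is the mean of its probes' log2 ratios. In 5923 genes with several probes, the median SD between probes was 0.10. No gene had probes at least 2-fold apart from 0 in opposite directions. The software's error of a ratio was propagated from its error of each processed signal. Signal-scaled errors of this kind cover the measurement on the array and not the variation between plants.

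Probes were named through RefSeq accessions in the files and a gene table of assembly TAIR10.1, used for names only. It named 34263 probes by accession and 1277 by the locus name in the file, 475 matched several genes, and 7584 matched none, which gave 25878 genes; 6587 of these had no value because no probe gave one. Probe coordinates are those of the files (TAIR10). Exon and UTR positions were not used here. Symbols in the lists that the table does not know were replaced by its own. The probes of 8 spike-in RNAs had a median log2 ratio of 0.14 after scaling (range 0.09 to 0.23).

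With 1 array per group no test was possible and no p-value is given. Genes at least 2-fold different (log2 ratio of 1 or more, or -1 or less) were counted. For 29 gene lists the median log2 ratio of the members with a value was placed among 10000 random lists of the same size, drawn within 20 bins of mean signal, where at least 5 members had a value. The genes named in the text are LKP2, ZTL, FKF1 and GI; the 12 highest and 12 lowest genes measured on both arrays; the 5 largest bounds in each direction; all morning and evening clock genes; and, for every other list, the 4 members farthest from 0 and any member at least 2-fold different. A few other list members, and the named members of gene families, are given as context and were chosen after their values were seen. The lists, the rule for named genes and the alternatives were fixed before the data were examined. These alternatives were normexp background correction with an offset of 50, quantile normalisation, cyclic loess, median scaling, the authors' value table, the stricter and the absent background filter, the probe of highest signal per gene and higher thresholds. Scaling to the spike-in RNAs was added after seeing the data, as were 25 gene families found by words in the probe descriptions and a list of 12 leaf growth regulators.

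The counting and list steps were tested on simulated data made from the GFPox levels with the noise of the repeated spots, over 19173 genes of which 200 were changed for the comparison of GFP-LKP2ox with GFPox. Of 50 genes changed 1.5-fold, 0 were called at the 2-fold threshold; of 50 changed exactly 2-fold, 24 were called; and all 50 changed 3-fold and all 50 changed 4-fold were called. None of the 18973 unchanged genes was called. Of 100 random lists of 12 unchanged genes, 8 fell in the outer 2.5% at either end, and all 100 lists shifted by 0.3 reached the highest 2.5%. The simulated noise had an SD of 0.07, against a median software error of 0.20 and an SD of 0.42 among the real ratios. It held no variation between plants. The simulation therefore checks the counting and list steps and gives no rate of false calls for the real data. Computation used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.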

Results

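Transcript levels were measured in rosette leaves of Arabidopsis thaliana (ecotype Col-0) that carried 1 of 2 transgenes under the 35S promoter, a strong viral promoter active in most plant tissues. GFPox plants expressed green fluorescent protein alone and served as the control. GFP-LKP2ox plants expressed green fluorescent protein fused to LOV KELCH PROTEIN 2 (LKP2), an F-box protein with a blue-light-sensing LOV domain and a close relative of ZEITLUPE (ZTL) and FKF1, which act in the circadian clock and in the timing of flowering. Plants were 32 days old, had been grown at 22 °C in long days of 16 h light and 8 h dark, and were harvested, per the labels, at ZT0, the start of the light period. Each group was measured on 1 one-colour array, so there were no replicates, no difference could be tested, and "higher" and "lower" compare 2 RNA samples. The arrays lay on different slides, so slide and group cannot be told apart. Of 43803 gene-probe spots, 30645 (70.0%) were well above background on the GFPox array and 30228 (69.0%) on the GFP-LKP2ox array, and none was saturated. Ratios are GFP-LKP2ox over GFPox throughout. With a single array per group the precision of a group difference cannot be estimated. Of 50 probes with repeated spots, 16 were well above background on both arrays, and their median SD of the log2 ratio between spots was 0.07. The scanner software's own error of a gene's log2 ratio had a median of 0.20. Both describe the measurement on the array and leave out variation between plants, as do the software errors given below.

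The comparison asked which leaf transcripts differ when GFP-LKP2 is overexpressed. LKP2 itself had the highest ratio of all genes measured on both arrays, 21.7-fold higher in GFP-LKP2ox (log2 ratio 4.44, software error 0.20), with a signal of 13025 against 676 in GFPox, which goes with the labels of both samples. Its single probe lies on chromosome 2 at 8194792 to 8194851 (TAIR10, as the scanner file gives it); whether this is coding sequence or untranslated region was not determined here, so whether the probe reads the transgene, the endogenous gene or both is not known. ZTL was 2.45-fold lower in GFP-LKP2ox (log2 ratio -1.29, software error 0.20), with signals of 945 against 2608 at its single probe on chromosome 5 at 23244196 to 23244255. FKF1 had a log2 ratio of 0.15 over 2 probes. GIGANTEA (GI), which binds all 3 of these F-box proteins, had a log2 ratio of 0.56, and its 2 probes gave 0.55 and 0.58.

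Across the 19291 genes with a value, 400 were at least 2-fold higher in GFP-LKP2ox and 405 were at least 2-fold lower. Of these, 63 of the higher and 81 of the lower genes were not well above background on the dimmer array and entered with a lower bound on their fold. Large differences lay mostly on the lower side, with 12 genes at least 4-fold higher and 56 at least 4-fold lower. The genes' log2 ratios had a median of 0.02, and the SD over the 18542 genes measured on both arrays was 0.42. Higher genes made up 49.7% of the calls in the main setting, 36.8% (287 against 492) after cyclic loess and 29.9% (240 against 564) when the arrays were scaled to their spike-in RNAs, a scaling that moved the median of all genes by -0.15. They made up 50.8% (337 against 327) over probes well above background on both arrays and 52.1% (806 against 740) without a background filter. Normexp background correction left 100 higher and 146 lower genes, and a log2 threshold of 1.5 left 83 and 137.

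**Figure D1:**
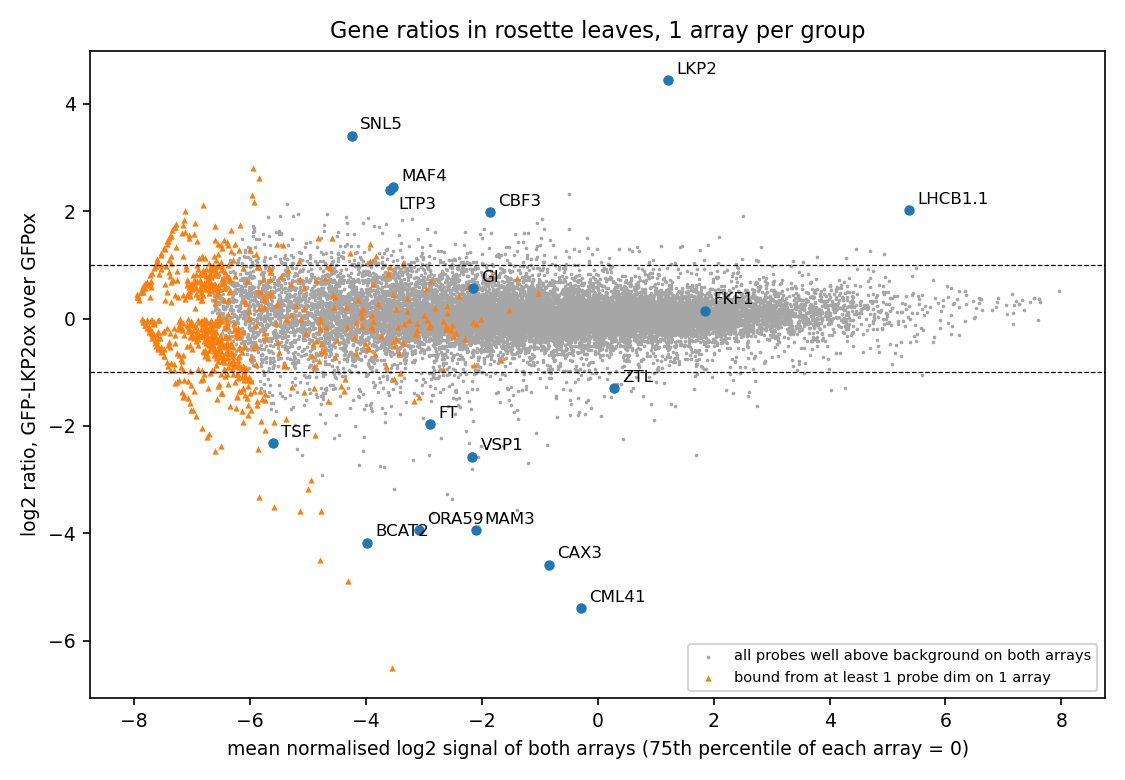
Each point is 1 gene. The x axis is the mean normalised log2 signal of both arrays and the y axis is the log2 ratio of GFP-LKP2ox over GFPox; dashed lines mark 2-fold, orange triangles are genes with at least 1 probe dim on 1 array, whose ratio is or includes a bound, and blue points are labelled genes, of which TSF is a bound. LKP2 stands highest at 4.44, and CML41 is lowest among genes measured on both arrays at -5.40.

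After LKP2, the highest genes measured on both arrays were SNL5, a Sin3-like protein, at 10.6-fold, MAF4, a MADS-box relative of the flowering repressor FLC, at 5.44-fold, and the lipid-transfer protein gene LTP3 at 5.23-fold. LTL1, a GDSL lipase, was 4.96-fold higher and LHCB1.1, a light-harvesting protein of photosystem II, was 4.06-fold higher. CBF3, an activator of cold-response genes, was 3.93-fold higher. The remaining 5 of the 12 highest, AT3G61028, AT4G29020, AT1G31670, AT3G05600 and AT5G12970, lay between 3.76-fold and 4.38-fold. The lowest gene was CML41, a calmodulin-like calcium-binding protein, 42.1-fold lower in GFP-LKP2ox (log2 ratio -5.40), with a signal of 153 against 7255. CAX3, a vacuolar cation/proton exchanger, was 23.9-fold lower, and BCAT2, a branched-chain amino acid aminotransferase, was 18.0-fold lower. ORA59, a transcription factor of the combined jasmonate and ethylene response, was 15.4-fold lower, as MAM3, a chain-elongation enzyme of aliphatic glucosinolate synthesis, was 15.3-fold lower. WRKY26 was 12.4-fold lower, AT1G21550, annotated as a calcium-binding protein, 11.9-fold, the glutaredoxin GRX480 10.3-fold, the MATE transporter AT3G23550 9.62-fold and the transcription factor TCP1 9.02-fold. AT5G38780 was 7.55-fold lower, and AT2G32487 had a log2 ratio of -2.81. In GFP-LKP2ox the signals of BCAT2 (18.1) and AT5G38780 (16.4) were near the lowest signal well above background there (11.6), so their folds are uncertain too.

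Among genes not well above background in 1 sample, the largest bounds also lay on the lower side. AACT1 (AT5G61160), annotated as an anthocyanin acyltransferase, was at least 91.4-fold lower in GFP-LKP2ox and AT1G54575 at least 29.4-fold. AT5G64190 was at least 11.9-fold lower and AT4G01390 at least 11.4-fold. AT5G20790 was 11.9-fold lower as observed, since its own dim signal of 12.9 was used, and its true fold may be smaller or larger. In the other direction, CYP96A15, a hydroxylase of wax alkanes, was at least 6.95-fold higher, followed by AT5G02580 at 6.10-fold, AT2G16210 at 4.94-fold, OFP12 at 4.53-fold and B70 at 4.31-fold, each as a lower bound.

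Gene lists fixed before the data were examined were then compared, 29 in all. For the 26 lists with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size matched on signal, as a description of these 2 samples. The medians of 6 lists lay in the highest 2.5% of random lists and those of 9 in the lowest 2.5%. Random lists draw genes independently, whereas members of a fixed list may vary together between any 2 samples. Percentiles near the ends are therefore reached more readily and are no measure of an effect of the transgene.

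Core clock genes differed little at the 1 harvest time sampled, which cannot show a shift in timing or amplitude. Some morning genes were dim, with GFPox signals of 38.4 for CCA1 and 51.4 for LHY. Of 11 measured morning genes, 1 was at least 2-fold higher, RVE7 at 2.42-fold, a mean that includes a bound, and the list's median of 0.04 lay at percentile 49.0. CCA1 had a log2 ratio of 0.68, PRR7 of 0.50, AT5G52660 of 0.31, LNK1 of 0.12, LNK2 of 0.04, RVE8 of -0.03, RVE4 of -0.10, RVE2 of -0.23, RVE1 of -0.27 and LHY of -0.27, and PRR9 was not well above background on either array. None of the 10 evening genes reached 2-fold, and their median of 0.07 lay at percentile 69.0. GI (0.56), LUX (0.35), PRR5 (0.31), TCP21 (0.28) and FKF1 (0.15) lay above 0, and BOA (-0.02), PRR3 (-0.04), ELF4 (-0.12), ELF3 (-0.24) and TOC1 (-0.37) lay below. Both medians lay below 0 with spike-in scaling, at -0.10 and -0.08. Genes of the clock's output had a median of 0.42 at percentile 99.9 (0.27 with spike-in scaling). In that list LHCB1.1 exceeded 2-fold, CDF3 stood at 0.78, CAT3 at 0.55 and COL1 at -0.60.

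Flowering-time genes differed in both directions, with 1 of 21 measured members at least 2-fold higher and 2 lower. FT, the mobile signal that induces flowering, was 3.91-fold lower in GFP-LKP2ox (log2 ratio -1.97), and its close relative TSF was at least 4.99-fold lower, while MAF4 was 5.44-fold higher. SPL5 had a log2 ratio of 0.91, FUL of -0.78, SOC1 of -0.72, FLC of -0.65 and CO of -0.46, and LFY and AP1 were not well above background on either array. The median of the list was 0.00 at percentile 39.7 (-0.14 with spike-in scaling) and its mean was -0.11. Of 9 flower and meristem markers, SEP1 (AT5G15800) was at least 5.40-fold lower in GFP-LKP2ox and AG had a log2 ratio of 0.16. SEP3 was well above background in GFPox alone, too close to the floor to give a fold, and AP3, PI, SEP2, STM, WUS and KNAT1 were not well above background on either array.

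Jasmonate and ethylene genes formed the list with the most lower members, 11 of 19 at least 2-fold lower in GFP-LKP2ox and none at least 2-fold higher. Besides ORA59, the vegetative storage protein gene VSP1 was 5.94-fold lower, the defensin gene PDF1.2A 4.72-fold, the jasmonate repressor gene JAZ5 3.20-fold and the biosynthetic gene AOC1 3.06-fold. VSP2, PR4, PDF1.2B, PR3 and ERF1 were also lower, by 2.77-fold, 2.58-fold, 2.57-fold, 2.53-fold and 2.27-fold, and JAZ9 had a log2 ratio of -1.20. JAZ10 alone of the 19 lay above 0, at 0.61. The list's median of -1.20 lay below all 10000 random lists (percentile 0). VSP1 and VSP2, PDF1.2A and PDF1.2B, and AOC1 and AOC2 are pairs of similar sequence, so the assignment of signal within each pair is uncertain. Salicylic acid and defence genes had a median of -0.23 (percentile 0.04; -0.38 with spike-in scaling), with WRKY38 2.14-fold lower, CBP60G at -0.96 and WRKY70 at -0.65, while PR5 stood at 0.96. None of the 9 touch and wound genes reached 2-fold. Their median was -0.19 (percentile 2.1, or 4.2 with the highest-signal probe per gene), with WRKY40 at -0.75, ZAT10 at -0.73, TCH4 at 0.61 and WRKY33 at -0.44.

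Glucosinolate genes were lower as a group, with 18 of 20 below 0, 3 at least 2-fold lower and a median of -0.69 (percentile 0). MAM3, CYP79F2 (3.93-fold) and BCAT4 (2.61-fold) passed 2-fold, all of them enzymes of the methionine-derived pathway, and MAM1 stood at -0.96. CYP79F1 and CYP79F2 are near-identical neighbours, so their values are uncertain as to which copy was measured. Phosphate-starvation genes had a median just under -1 (percentile 0) and a mean of -0.89, with 4 of 8 at least 2-fold lower. MGD3 was 2.96-fold lower, GDPD1 2.74-fold, a value that includes a bound, and PEPC1 and SPX3 entered with bounds at log2 ratios of -1.14 and -1.04. Their median was -0.39 with normexp. Iron-response genes split: the iron-storage gene FER1 was 3.62-fold higher and FER4 stood at 0.91, whereas the iron-deficiency genes AT1G47400 and AT1G47395 were 4.97-fold and 2.81-fold lower, BHLH101 was at least 2.54-fold lower and OPT3 stood at -0.76. The median of the 7 members was -0.76 (percentile 0.01) and turned to 0.34 without the background filter. It was -0.19 with normexp and -0.21 (percentile 3.4) over probes well above background on both arrays. Of the 5 nitrate genes, with a median of -0.22 (percentile 1.5), the nitrate reductase gene NIA1 was 2.02-fold lower, and NIA2 stood at -0.46, NRT1.1 at 0.34 and NIR1 at -0.22. In the sugar-starvation list (12 measured, median -0.15, percentile 3.0, or 0.01 with the highest-signal probe per gene), BCAT2 and the F-box gene KFB20 (2.03-fold) were lower and ASN1, an asparagine synthetase gene, was 2.83-fold higher, a value that includes a bound, and TPS9 stood at -0.59. None of the 17 starch genes reached 2-fold, and their median was 0.10 (percentile 74.4), with GBSS1 at 0.42, DPE1 at 0.35, PHS1 at 0.25 and PWD at -0.23; with spike-in scaling it was -0.05.

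Photosynthesis and chlorophyll genes were higher as a group, with 18 of 21 above 0, none lower than -0.20 and a median of 0.46 (percentile 100). With quantile normalisation the median was 0.27. The photosystem II antenna genes LHCB2.1 and LHCB2.2 were 3.18-fold and 2.88-fold higher, LHCB3 was also more than 2-fold higher, and LHCA4 stood at 0.92. These are means over probes that differed. The probes' log2 ratios ran from 1.21 to 2.13 for LHCB2.1, from 0.69 to 2.18 for LHCB2.2 and from 0.89 to 1.52 for LHCB3. For LHCB2.2 and LHCB3 at least 1 probe thus lay below 2-fold. The mean unscaled signals over the 3 LHCB2.2 probes were 57117 in GFPox and 82651 in GFP-LKP2ox, which differ by far less than 2.88-fold. Most of the LHCB2.2 signal therefore went with the low end of its range, and the dimmer probes raised the mean ratio. LHCB1.1 and the LHCB2 genes have near-identical copies, so which copy was measured is uncertain. All 11 cell division genes lay above 0, with a median of 0.80 (percentile 100). The kinase gene CDKB2;1 was 2.07-fold higher, the ribonucleotide reductase gene TSO2 2.05-fold and CDKB1;1 2.04-fold, and KNOLLE, which acts in cytokinesis, stood at 0.99. Of 17 guard cell and stomatal genes, 16 lay above 0 and 4 were at least 2-fold higher (median 0.34, percentile 99.9; 0.19 with spike-in scaling). Those 4 act in the formation of stomata: SDD1 was 3.29-fold higher, MUTE 2.99-fold, TMM 2.69-fold and SPCH 2.39-fold, whereas FAMA, which also acts in their formation, stood at 0.10, EPF1 at 0.50 and EPF2 at 0.89 as a bound. The guard cell channel genes KAT1 and SLAC1 had log2 ratios of 0.25 and 0.13. Vascular markers had a median of 0.21 (percentile 97.3; 0.07 with spike-in scaling, and percentile 97.7 without the background filter), with the xylem protease gene XCP1 2.00-fold higher, CESA8 at 0.76, and the sugar exporter genes SWEET11 and SWEET12 at -0.84 and -0.75.

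Dehydration-inducible genes were higher as a group, with 24 of 29 above 0 and a median of 0.37 (percentile 100; 0.22 with spike-in scaling). LTP3, RD29A (2.46-fold) and COR15A (2.40-fold) were at least 2-fold higher, P5CS1 and LTI30 both stood at 0.99, and the NAC factor gene ANAC055 was at least 3.25-fold lower. LTP3 has a similar neighbour, LTP4, that was not well above background on either array. In the list of DREB and cold-response regulators, 3 of 9 were at least 2-fold higher: CBF3, CBF1 (2.07-fold) and CBF2 (at least 3.04-fold), which are tandem genes of similar sequence. ZAT10 and ZAT12 in that list stood at -0.73 and -0.62. The list's median was 0.34 (percentile 96.7; 0.19 with spike-in scaling) and turned to -0.12 over the 7 members well above background on both arrays. Genes of abscisic acid synthesis, breakdown and signalling showed no common direction, with a median of 0.06 (percentile 73.4; -0.09 with spike-in scaling) and a mean of -0.02 over 29 members. The phosphatase gene HAI1 was 2.01-fold higher, the receptor gene PYL5 (2.48-fold) and the catabolic gene CYP707A4 (at least 2.04-fold) were lower, and CYP707A2 stood at -0.85.

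PIF and auxin-response genes had a median of 0.28 (percentile 99.8; 0.13 with spike-in scaling) with 18 of 24 above 0. YUC9 was at least 2.52-fold higher, GH3.3 was 2.07-fold lower, HFR1 was lower by just under 2-fold, IAA5 stood at 0.92 and PIL1 at 0.88. Among 20 photoreceptor and light-signalling genes the median was 0.05 (percentile 70.0), and BBX28, at 2.04-fold higher, was the 1 member past 2-fold; BBX16 stood at 0.68, BBX22 at 0.56 and RUP1 at -0.46. With spike-in scaling that median was -0.10. Of 13 measured flavonoid genes, 4 were at least 2-fold higher and 1 lower, with a median of 0.01 (percentile 43.6; -0.14 with spike-in scaling). MYB111 (3.56-fold), FLS1 (2.49-fold), CHS (2.21-fold) and 4CL3 (2.02-fold) were higher, and PAP1 (AT1G56650), a regulator of anthocyanin formation, was 2.46-fold lower. DFR, an enzyme gene of anthocyanin formation, was well above background in GFPox alone, too close to the floor to give a fold.

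Heat shock genes had a median of -0.32 (percentile 0.35) over 9 measured members, with HSP70 2.02-fold lower, GolS1 at -0.87, HSP18.2 at 0.83 and HSFA7A at -0.52; the median was 0.14 without the background filter. Senescence genes had a median of -0.17 (percentile 1.8, or 2.8 with the highest-signal probe per gene; -0.32 with spike-in scaling). In this list ORE1, a NAC regulator of leaf senescence, was 2.49-fold lower, SAG21 stood at -0.89, SAG13 at 0.61 and XTH24 at -0.51, and SAG12 was not well above background on either array. The 4 measured root markers, FRO2 at 0.49, NRT2.1 at 0.48, SHR at 0.05 and TIP2;3 at -0.09, all lay within 2-fold. So did the 13 reference genes, with a median of 0.07 (percentile 52.8; -0.08 with spike-in scaling), of which AT5G60390, an elongation factor gene, was farthest from 0 at 0.66, followed by TUB2 at 0.24, GAPC1 at 0.23 and YLS8 at 0.19.

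**Figure D2:**
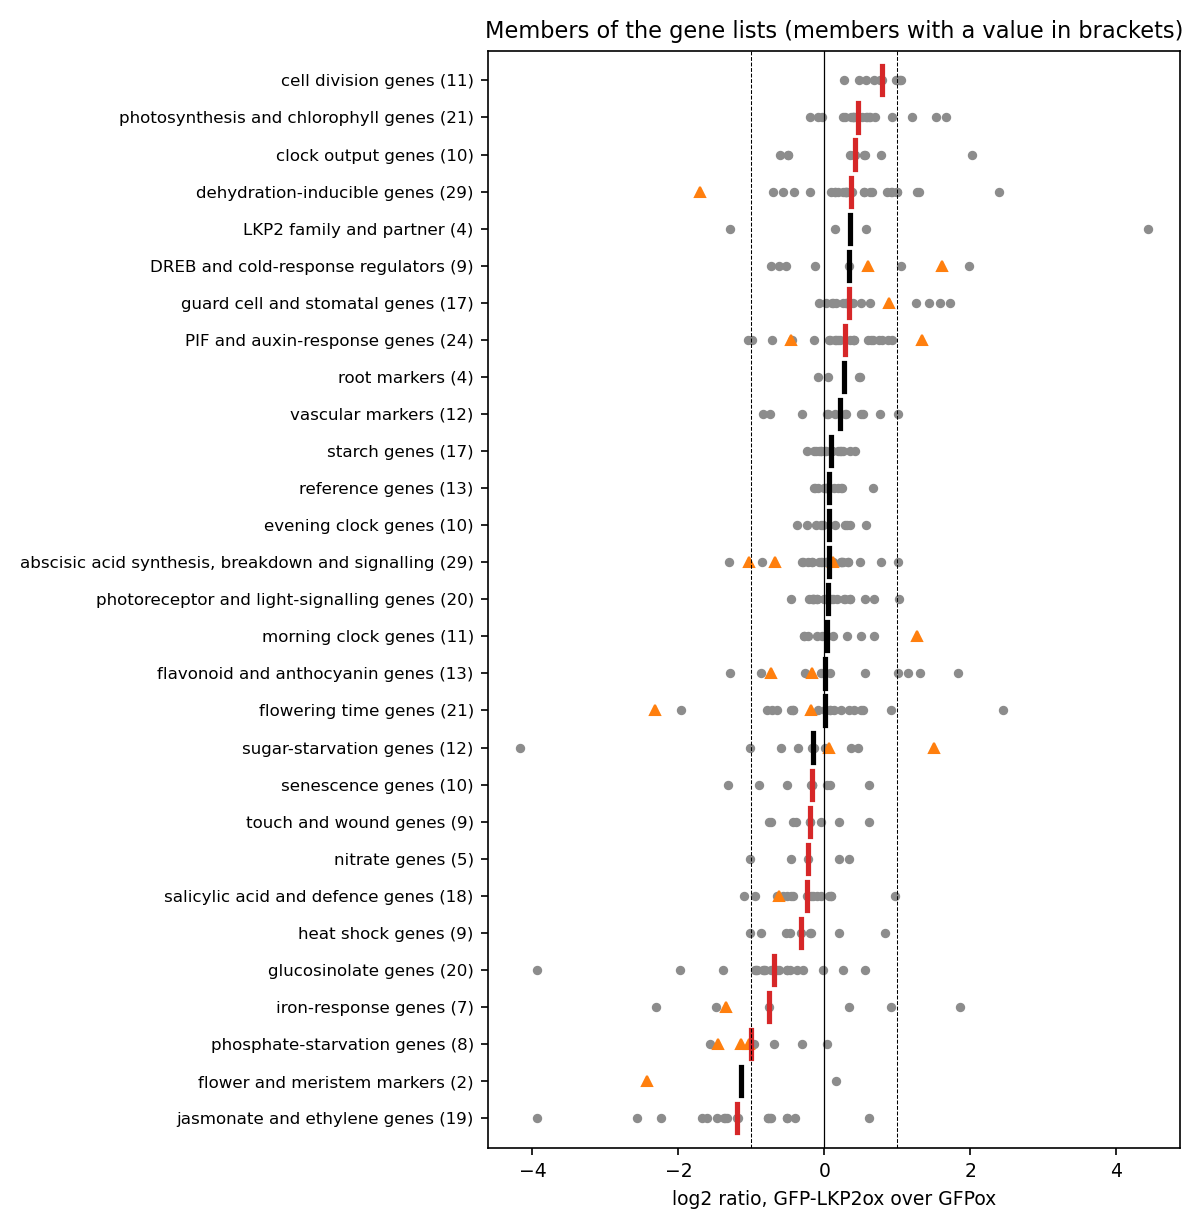
Rows are the 29 gene lists, with the number of members that have a value in brackets, and the x axis is the log2 ratio of GFP-LKP2ox over GFPox. Grey points are members measured on both arrays, orange triangles are members whose ratio is or includes a bound, and bars are medians, red where the median lay in the highest or lowest 2.5% of matched random lists; the medians run from -1.20 for the jasmonate and ethylene genes to 0.80 for the cell division genes.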

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

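Apart from the list of leaf growth regulators, whose expected outcome was written down before its values were seen, the tests in this part were chosen after the results were seen.

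Probes that name no single gene lay outside the comparisons above. Of 3567 such probes with a value, 107 were at least 2-fold above the control array and 71 at least 2-fold below it. The highest of those measured on both arrays, A_84_P750244 on chromosome 1 at 25991521 to 25991580 (TAIR10, file annotation), was 10.1-fold higher, with a signal of 209 against 23.3; what it detects was not determined.

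Cell division genes were higher in GFP-LKP2ox, all 11 above 0 and 3 of them at least 2-fold. A trend of the ratio with signal is argued against as the whole cause, since the cell division median stayed at 0.75 after cyclic loess. Spike-in scaling, which moves all ratios by about the same amount, left that median at 0.65. It shows only that a scaling error of the size seen in the spike-ins is too small to be the whole cause. A biological hypothesis is that the GFP-LKP2ox leaves were at a less advanced stage of growth; the test was a list of 12 leaf growth regulators (GRF factors, GIF1, ANT and others), none of them in another list, of which 9 were measured. Their median of 0.08 lay at percentile 65.3, which by the rule written beforehand counted against the hypothesis. That rule took no account of members that went both ways, and 6 lay above 0 and 3 below. Members on both sides of 0 are usual where a median lies near 0, so they do not undo the failed prediction. The test counts against the hypothesis for these 9 regulators in these 2 samples, and does not exclude it. The senescence list had a median of -0.17 at percentile 1.8, which became 2.8 with the highest-signal probe per gene. A difference between slides stays open.

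Jasmonate and ethylene genes were lower in GFP-LKP2ox, equally readable as higher in GFPox. A trend with signal is argued against as the whole cause by a median of -1.26 after cyclic loess. Handling of the GFPox leaves before freezing stays open, since the touch and wound list had a median of -0.19 at percentile 2.1, which became 4.2 with the highest-signal probe per gene; the jasmonate list stood at -1.20. So does a pathogen that raises salicylic acid genes, whose list had a median of -0.23 at percentile 0.04. Attack by insects, a plant-to-plant difference and an effect of GFP-LKP2 itself were not tested and could not be separated with 1 sample per group.

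ZTL was lower in GFP-LKP2ox while LKP2 was higher. With spike-in scaling, which moves all ratios by about the same amount, the log2 ratio of ZTL was -1.44, where the main setting gave -1.29. A scaling error of the size seen in the spike-ins therefore does not account for the lower ZTL, and no more than that is shown. A defect of the spot cannot be told apart from a true difference, because ZTL had 1 spot on each array. Reduced ZTL transcript through feedback or through silencing by the related transgene is a hypothesis that was not tested.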

How the results depend on the processing

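All alternatives except the spike-in scaling were planned; that one was chosen after seeing the data. No paired analysis was possible because each group holds 1 sample. LKP2 kept its log2 ratio between 4.26 and 4.44 in every setting. No named gene at least 2-fold different changed sign in a setting that gave it a value. Of the 158 named genes, with normexp, which pulls dim ratios towards 0 through its offset, 68 moved by more than their software error. So did 30 with spike-in scaling, 21 with the highest-signal probe per gene and 14 without the background filter. With quantile normalisation and with cyclic loess 3 moved, and 19 had no value over probes well above background on both arrays. Of the 15 lists in the outer 2.5% of random lists, all 15 stayed there under quantile normalisation, cyclic loess and normexp. All 15 also stayed under median scaling, spike-in scaling and the authors' table. Each of those differs from the main setting by a constant per array, so it could hardly move a percentile. The authors' table is itself scaled to the median and repeats that setting. With probes well above background on both arrays 14 stayed (not iron-response genes). Without the background filter 13 stayed (not heat shock and iron-response genes). With the highest-signal probe 13 stayed (not touch and wound genes, at percentile 4.2, and senescence genes, at 2.8). Other lists entered the outer 2.5%: sugar-starvation genes, at percentile 2.2 with normexp, 1.6 with probes well above background on both arrays, 2.0 without the filter and 0.01 with the highest-signal probe; vascular markers, at 97.7 and 98.1 with the last 2; and DREB and cold-response regulators, at 97.6 without the filter. For the values that follow, the cause was not tested unless given. The counts of genes at least 2-fold higher and lower (400 and 405) became 100 and 146 with normexp, 806 and 740 with no background filter, which lets in noise at the floor, 240 and 564 with spike-in scaling, 83 and 137 at a log2 threshold of 1.5, and 12 and 56 at a threshold of 2, the last 2 pairs by construction. They were 337 and 327 over probes well above background on both arrays, which leaves out bounds, and 287 and 492 with cyclic loess. Of the list medians, with normexp the jasmonate and ethylene genes stood at -0.81, the iron-response genes at -0.19, the phosphate-starvation genes at -0.39 and the flower and meristem markers at -0.34. With probes well above background on both arrays, DREB and cold-response regulators stood at -0.12, iron-response genes at -0.21 and flower and meristem markers at 0.16, from 1 member. Without the background filter heat shock genes reversed to 0.14, iron-response genes reversed to 0.34, and flower and meristem markers stood at 0.16; with cyclic loess the last stood at -0.034. Photosynthesis and chlorophyll genes stood at 0.27 with quantile normalisation, 0.32 with cyclic loess and 0.31 with spike-in scaling. Nitrate genes stood at -0.38 with quantile normalisation and -0.36 with spike-in scaling, touch and wound genes at -0.34 with spike-in scaling, and sugar-starvation genes at -0.34 with the highest-signal probe and -0.30 with spike-in scaling. Medians near 0 took the other sign not only with spike-in scaling but also with quantile normalisation (morning, flowering time, flavonoid, starch and reference genes), cyclic loess (the same except starch), median scaling and the authors' table (flowering time and flavonoid genes), no background filter (flavonoid genes) and the highest-signal probe (flowering time genes). Signal over background limits the dim genes: the SD of the log2 ratio was 0.61 in the dimmest of 10 equal groups of genes and 0.33 in the brightest.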

Other observations

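Further gene groups were formed after seeing the data, from words in the probe descriptions, 25 in all; the median of each was set among 10000 signal-matched random lists as before. Arabinogalactan proteins, which sit in the cell wall, had a median log2 ratio of 0.68 over 42 genes, 11 of them at least 2-fold higher, among them AGP22 at 2.65-fold and AGP7 at 2.59-fold. Histones stood at 0.68 over 46 genes with 42 above 0, tubulins at 0.47 over 24 genes with TUB1 3.20-fold higher, expansins, which loosen cell walls, at 0.48 over 21 genes with EXLA2 2.55-fold higher, and xyloglucan transferases at 0.42 over 35 genes with XTH8 3.19-fold higher and XTH25 2.57-fold lower. Aquaporins stood at 0.50 over 29 genes with PIP2;5 at a log2 ratio of 1.63, and chlorophyll a/b-binding proteins at 0.54 over 24 genes, 12 of them also in the fixed lists. All 41 chloroplast ribosomal protein genes lay above 0 (median 0.47), as did 197 of 205 cytosolic ones (median 0.31), and none of them reached 2-fold. Lipid-transfer proteins (0.38), SAUR genes (0.35), GDSL lipases (0.33) and kinesins (0.17) also had positive medians. Peroxidases had a median of 0.24 but a mean of 0.09, with 4 of 33 at least 2-fold higher and 3 lower, among them AT2G37130 at 6.42-fold lower. Each of these medians stayed above 0 under normexp, quantile, median, cyclic loess and spike-in scaling; the last gave 0.16 for cytosolic ribosomal proteins, 0.23 for lipid-transfer proteins, 0.20 for SAUR genes, 0.19 for GDSL lipases, 0.09 for peroxidases and 0.03 for kinesins.

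TIR-NBS-LRR resistance proteins had a median of -0.29 with 53 of 59 below 0, and none of them reached 2-fold. WRKY factors stood at -0.26 over 56 genes with WRKY26 and WRKY65 12.4-fold and 3.04-fold lower, and NAC factors at -0.17 over 58 genes with 8 at least 2-fold lower. Cytochrome P450s (-0.17), F-box proteins (-0.10) and glutathione S-transferases (-0.08) also had negative medians. All of these stayed below 0 under the same 5 scalings. They lay nearer to 0 with normexp, at -0.19 for TIR-NBS-LRR proteins, -0.08 for WRKY factors and -0.06 for NAC factors. Normexp gave -0.09 for cytochrome P450s, -0.06 for F-box proteins and -0.04 for glutathione S-transferases. With spike-in scaling they lay farther from 0, from -0.23 for glutathione S-transferases to -0.43 for TIR-NBS-LRR proteins. Calmodulin-like proteins had a median of -0.05 but 5 genes at least 2-fold lower, among them CML41 at 42.1-fold. Glucosyltransferases by description, a group that takes in some xyloglucan enzymes (-0.04), MYB factors (-0.02), pentatricopeptide repeat proteins (0.00) and ethylene response factors (0.05) lay near 0, the last 3 with a sign that differed between scalings.

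CCA1 and LHY, which belong to the morning genes of the clock, had signals of 38.4 and 51.4 in GFPox and 54.7 and 37.8 in GFP-LKP2ox, and PRR9 was not well above background on either array, although the harvest is labelled ZT0.

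Genes with only some probes dim on 1 array were named by rule only as list members. AT4G16260, in no list, chosen after its values were seen and annotated as a hydrolase, was 22.6-fold lower in GFP-LKP2ox (log2 ratio -4.50), a value that includes bounds from 2 of its 3 probes, and its probes ranged from -5.94 to -3.78.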
